A study of Mus musculus with 6 samples.

How the data were processed

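Gene expression was measured in 6 RNA libraries of sorted mouse CD4+ T cells, 3 in the Cocktail group and 3 in the Control group, grouped by the sample titles. Per the labels' protocols, parents in the Cocktail group received 0.5 g/l of each of 4 antibiotics in water with 4 g/l of the sweetener Splenda, and pups of both groups were weaned on day 21. Libraries were made from 150 ng of RNA (RIN above 8) with a stranded poly-A kit and sequenced with paired reads of 100 cycles, per the labels' protocols. TopHat2, Cufflinks and the mm9 build were used, per the submitters' processing notes. Versions, annotation, strand setting and filters are not given in the sources used here, and without the strand setting overlapping and antisense genes cannot be told apart.

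The authors deposited FPKM values for 30121 assembled loci, 6734 of them without a gene name and 638 naming more than 1 gene. The deposited log2 ratios of the authors' comparison equal the log2 of the mean Control over the mean Cocktail FPKM for the 2173 finite loci within 0.0001, and 6 are infinite, so their sign was turned here. The deposited p-values and q-values reach at most 0.00665 and 0.0498, and 802 loci share the lowest p-value, 5e-05. The low FPKM values do not give whole reads back, so depth is known only as relative steps between some libraries, and precision was judged from the spread between libraries.

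Loci with a mean of at least 1 FPKM over the 6 libraries were kept (11767, of which 10043 have a gene name). The log2(FPKM + 1) values were tested with limma 3.58.1 in R 4.3.3 with an intensity trend, 2-sided, with Benjamini-Hochberg adjustment at 0.05. Fold changes are on the log2(FPKM + 1) scale, which understates the change of low genes. A gene name carried by more than 1 locus (702 names) stands for its most abundant locus unless stated. Some named genes share their locus with another gene: Ifi47 with Olfr56, Psmb10 with Ctrl, Foxp3 with 4930524L23Rik and Cd74 with Mir5107. Of the tested loci, 61 were listed at 0 in at least 1 library. Gene lists were 37 sets fixed before the data were examined, tested with camera at a preset correlation of 0.01 over the 35 with at least 2 tested members, and adjusted over these. The list of mitochondrially encoded genes had 0 members under its names and was not analysed here. The list for the sex of the animals had 1 tested member, Xist, at 43.2 ± 9.39 FPKM in Cocktail and 36.0 ± 6.44 FPKM in Control, which did not pass, except as higher with a replicate block or a term for replicate 1 (adjusted p 0.0490 and 0.0272). The named genes were chosen by a rule fixed before the data were examined: the 10 largest rises and falls past the threshold with groups that do not overlap, up to 4 members of each list with the smallest p, 14 T cell genes always considered, and the 5 largest rises and falls in the authors' deposited table. Genes named are a part of those the rule takes, apart from the more abundant Selplg locus, Eef1a1 and Gapdh, chosen after their values were seen.

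GC content and length of transcripts came from a reference of another build (GRCm38), used only for these and for names, and 99.5% of the tested named loci had both. No coordinates are given, since none were in the tables used. The correction for GC content and length removed from each library its own trend, fitted with natural splines of 5 and 3 degrees of freedom. It was added after the data were seen, in 2 versions. The version run before the other left the mean of each library as deposited and gave 225 higher and 722 lower loci. The version used in the texts, which removes the mean along with the trend, was chosen after those counts had been seen and gave 485 and 443.

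Other alternatives were other pseudocounts, filters, scalings, variance models and thresholds, a replicate block, leaving out each library, fry, camera on ranks and an estimated correlation, planned before the data were examined. The fry test asks whether the members of a list change at all, whereas camera asks whether they change more than the other loci. A term for replicate 1 against the other libraries, fits on replicates 2 and 3 alone, leaving out loci at 0, summing loci of 1 name and combinations with the GC correction were added after the data were seen. On simulated Cocktail and Control libraries, 200 loci changed by a log2 of 0.5 were recovered at 50% over 11679 loci and by a log2 of 1 at 90% over 11673 loci, with 8 unchanged loci called in each. With a simulated trend on GC content, 2816 and 2926 unchanged loci were called without the correction, over 11623 and 11610 loci, and 8 and 9 with it, over 9902 and 9882 loci. The simulated noise was independent between loci, changed loci were picked without regard to GC content, and each Cocktail library had the same straight-line trend. The correction is built to remove such a trend, so these counts do not show how many of the real calls the trend gave. Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9 were used for tables and plots.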

Results

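RNA was sequenced from CD4+ T cells of the mouse spleen that were sorted as negative for Foxp3, the transcription factor of regulatory T cells, negative for CD25 and high for CD45RB, a surface phenotype of naive T cells. The donors were Foxp3 reporter mice on a C57BL/6 background. In the Cocktail group (n = 3) the parents had received vancomycin, streptomycin, ampicillin and metronidazole in sweetened drinking water, and the offspring drank sterile water after weaning. The Control group (n = 3) was raised without antibiotics and drank regular water after weaning, so the groups differed in the water given after weaning as well as in the treatment of the parents. The series addresses antibiotic exposure in early life and the CD4+ T cells of the offspring. Expression was given as FPKM, fragments scaled by transcript length and by the mapped total. Each library held between 11609 and 11883 loci of at least 1 FPKM. The number of reads behind these values is unknown. The steps between low values put Cocktail 2, Cocktail 3 and Control 2 at 1.06, 1.24 and 1.59 times the depth of Control 3, with no clear step in either replicate 1 library. Nothing in the labels says that the 3 samples of a group came from separate animals, so the p-values measure the spread between these samples, which may be technical.

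In Cocktail cells, genes of heat shock and cell dissociation stress, on a joint list, and of the type I interferon response were higher as groups. Genes of cholesterol synthesis, glycolysis and T cell activation were lower. These 5 of 35 fixed lists passed the camera test with a preset correlation. The activation list no longer passed it once the GC and length trend was removed (camera adjusted p = 0.220). None passed with an estimated correlation (lowest adjusted p = 0.836 with an estimated correlation). That correlation is estimated from only 4 residual degrees of freedom. Lists as unlike as heat shock and Th2 (camera adjusted p = 1.41e-05 and 0.546 with the preset correlation) share the value of 0.836. Such ties arise because the Benjamini-Hochberg adjustment can give many lists a common value, so they do not rank the lists. As camera calls, the 5 lists rest on the preset correlation. Values of some markers of other cells also differed between the groups. Hbb-b1 of red blood cells fell from 27.0 ± 9.93 to 2.40 ± 1.02 FPKM and Hba-a1 from 7.94 ± 2.53 to 0.481 ± 0.175 FPKM. The median log2 fold change was -0.46 for B cell and -0.52 for antigen presenting cell markers, whose lists did not pass (camera adjusted p = 0.0912 and 0.243). With the GC and length trend removed these medians were -0.34 and -0.36. Monocyte and macrophage markers had an uncorrected median of 0.0039, and those of CD8 T cells and NK cells of 0.069. Their lists did not pass either (camera adjusted p = 0.972 and 0.634). Cpt1a, which carries fatty acids into mitochondria, rose from 20.5 ± 1.78 to 44.4 ± 1.63 FPKM (mean ± SD, n = 3; log2 fold change 1.08, SE 0.077, adjusted p 0.00340, limma). Ddit4, an inhibitor of the growth kinase mTORC1, rose from 37.3 ± 2.43 to 78.8 ± 12.2 FPKM. Junb, a subunit of the transcription factor AP-1, fell from 221 ± 41.0 to 41.0 ± 9.64 FPKM. The cytokine genes Ifng and Tnf did not pass the test, with 2.85 ± 0.411 FPKM in Cocktail and 2.73 ± 0.236 FPKM in Control for Ifng and 10.5 ± 0.524 FPKM in Cocktail and 11.5 ± 1.57 FPKM in Control for Tnf.

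Of 11767 loci tested with limma, 1050 were higher and 2224 lower in Cocktail at an adjusted p under 0.05. Counts of list members below need to be read against the counts over all loci in this paragraph, since any set of loci would hold calls. The split depended on scaling, with 1779 higher and 2316 lower after median-of-ratios scaling and 2390 higher and 2033 lower after quantile normalization. Higher loci numbered 200, 389, 569, 327 and 288 without Cocktail 2, Cocktail 3, Control 1, Control 2 and Control 3 in turn, and lower loci 1200, 1477 and 1134 without Cocktail 2, Control 2 and Control 3. In 5733 loci, or 48.7% of those tested, the 3 Cocktail values did not overlap the 3 Control values, where chance gives 10%. The fold change followed the GC content of the transcript over 9995 named loci (Pearson r = -0.66, Spearman rho = -0.75, across genes, which are not independent replicates). Genes in the lowest decile by GC content had a median log2 fold change of 0.23 and those in the highest decile of -0.53. With each library's trend on GC content and length removed, 485 loci were higher and 443 lower, and 562 of 3032 uncorrected calls among these loci kept their call and direction, while 395 had a fold change of the other sign. With that trend removed but the mean of each library left as deposited, the counts were 225 and 722, and 325 of the 3032 had the other sign.

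The replicate 1 libraries of both groups stood apart from the other 4 libraries on the second principal component, which held 25.8% of the variance, while the first held 45.2% and separated the groups. Within replicates 2 and 3 of both groups, 1705 loci were higher and 2479 lower, and with the GC and length trend removed 1129 and 1030, where 431 of the 3032 uncorrected calls had the other sign. The correlation of fold change with GC content within these 4 libraries was -0.64 across genes. A model with a term for replicate 1 against the rest gave 2228 higher and 3059 lower loci. Replicate 1 alone holds 1 library per group, which allows no test. The mean correlation between libraries was 0.979 within groups and 0.964 between groups. The exact permutation p of 0.1 is the smallest that 10 splits of 6 libraries can give.

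**Figure D1:**
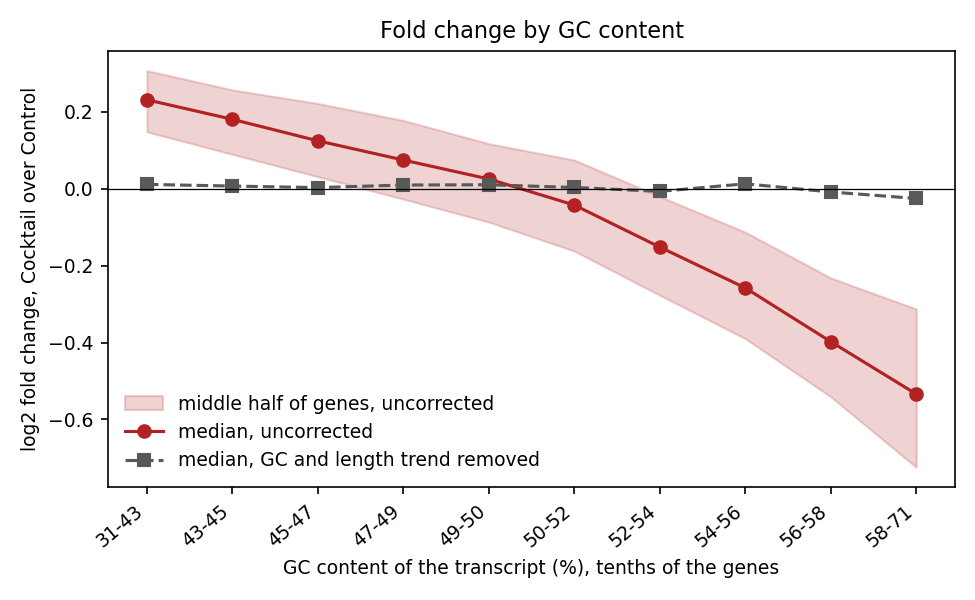
Median log2 fold change (Cocktail over Control, vertical axis) for deciles of 9995 named loci ordered by GC content of the transcript in percent (horizontal axis), as circles with the range between quartiles shaded, and as squares after the GC and length trend was removed. The uncorrected medians go from 0.23 in the lowest decile to -0.53 in the highest.

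Heat shock genes, most of which encode protein-folding chaperones, were higher in Cocktail. Their list was fixed as one of heat shock and dissociation stress, so it does not tell stress of cell preparation apart from other sources. Of 17 tested members of the list, 12 rose, 0 fell and 5 did not pass, and adjusted over the list alone 13 rose and 1 fell. Hspa1b rose from 3.12 ± 0.568 to 14.6 ± 2.65 FPKM (log2 fold change 1.92, SE 0.15, adjusted p 0.00340), and part of its reads may belong to its near-identical neighbour Hspa1a. Hsph1 rose from 42.8 ± 9.97 to 95.5 ± 10.0 FPKM (log2 fold change 1.16, SE 0.17, adjusted p 0.00717). Hspd1, a mitochondrial chaperone, rose from 28.2 ± 0.506 to 41.9 ± 1.82 FPKM (log2 fold change 0.55, SE 0.056, adjusted p 0.00353). Bag3, a cochaperone, was at 3.88 ± 0.276 FPKM in Cocktail and 4.69 ± 0.363 FPKM in Control, and Hmox1, which encodes a haem oxygenase, at 24.9 ± 4.79 FPKM in Cocktail and 36.4 ± 21.1 FPKM in Control, and neither passed. The list median was 0.45 (camera adjusted p = 1.41e-05, and adjusted p = 0.836 with an estimated correlation). With the GC and length trend removed the median was 0.44 and 11 members rose and 0 fell (adjusted p = 1.13e-08, and adjusted p = 0.454 with an estimated correlation). Beside this difference, with no trend removed, Hbb-b1 had a log2 fold change of -3.01, and the B cell and antigen presenting cell markers had medians of -0.46 and -0.52. The list passed in 27 of 29 alternatives, with adjusted p from 3.66e-12 to 0.836.

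**Figure D2:**
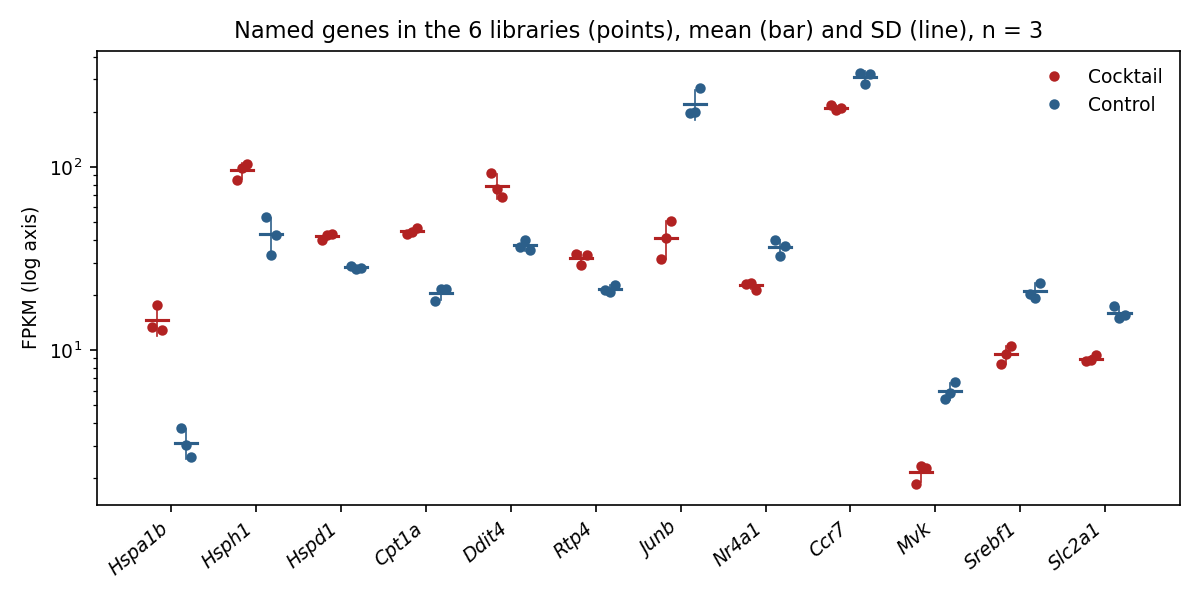
FPKM on a log axis for 12 named genes in the 3 Cocktail (red) and 3 Control (blue) libraries as points, with the mean as a bar and the SD as a line. In each gene the Cocktail points lie apart from the Control points, as in Cpt1a with means of 44.4 ± 1.63 and 20.5 ± 1.78 FPKM.

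Genes of cholesterol and fatty acid synthesis were lower in Cocktail, with 12 of 30 tested members lower, 0 higher and 18 not passing, and 12 lower adjusted over the list alone. Mvk, mevalonate kinase, fell from 5.96 ± 0.636 to 2.15 ± 0.259 FPKM (log2 fold change -1.14, SE 0.1, adjusted p 0.00340). Srebf1, a transcription factor of lipid synthesis, fell from 20.9 ± 2.17 to 9.45 ± 1.07 FPKM (log2 fold change -1.07, SE 0.11, adjusted p 0.00353). The list median was -0.23 (camera adjusted p = 0.00170, and adjusted p = 0.836 with an estimated correlation), and -0.20 with the GC and length trend removed (adjusted p = 3.35e-05, and adjusted p = 0.454 with an estimated correlation). Of the members 5 were then lower and 0 higher, with log2 fold changes of -0.65 for Mvk and -0.54 for Srebf1. Between the same libraries, with no trend removed, the log2 fold change was -3.01 for Hbb-b1, with medians of -0.46 for B cell and -0.52 for antigen presenting cell markers. The list passed in 27 of 29 alternatives, with adjusted p from 6.67e-06 to 0.836.

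Glycolysis genes were lower, with 6 of 19 tested members lower, 1 higher and 12 not passing, against 10 lower and 1 higher adjusted over the list alone. Slc2a1, the glucose transporter Glut1, fell from 15.9 ± 1.21 to 8.96 ± 0.349 FPKM (log2 fold change -0.76, SE 0.071, adjusted p 0.00352). Aldoa, an aldolase, fell from 226 ± 17.5 to 149 ± 11.1 FPKM. The list median was -0.26 (camera adjusted p = 0.0342, and adjusted p = 0.836 with an estimated correlation). With the GC and length trend removed the median was -0.11 (adjusted p = 0.0297, and adjusted p = 0.454 with an estimated correlation), with 2 members lower and 0 higher. Slc2a1 then had a log2 fold change of -0.42. Aldoa then did not pass (log2 fold change -0.60 before and -0.17 after). The list did not pass where the mean of each library was also left as deposited (adjusted p = 0.0567). It did not pass without Cocktail 2 or Control 1 (adjusted p = 0.0647 and 0.0667). With no trend removed Hbb-b1 had a log2 fold change of -3.01 here, and medians were -0.46 for B cell and -0.52 for antigen presenting cell markers. The list passed in 22 of 29 alternatives, with adjusted p from 0.0003 to 0.836.

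Among nuclear genes of oxidative phosphorylation, 23 of 74 fell and 1 rose (24 and 3 adjusted over the list alone), and the list did not pass (camera adjusted p = 0.219). Removing the GC and length trend gave 9 lower and 1 higher. The list passed as lower in 5 of 29 alternatives: without Cocktail 1 (adjusted p = 0.0157), within replicates 2 and 3 (adjusted p = 0.0317, and 0.0353 with the trend removed), without the filter and with fry (0.00948). It did not pass with an estimated correlation (adjusted p = 0.836 with an estimated correlation). The complex I subunit genes Ndufs7 and Ndufa2 fell, from 44.9 ± 1.70 to 20.8 ± 1.66 FPKM and from 86.4 ± 6.17 to 49.3 ± 0.202 FPKM, and Ndufs7 went from a log2 fold change of -1.07 to -0.57 with the trend removed. Uqcrb, a subunit of complex III, rose from 27.8 ± 3.84 to 36.9 ± 0.553 FPKM. Its call was lost without Cocktail 1, Cocktail 2, Cocktail 3, Control 2 or Control 3 (adjusted p 0.0506 to 0.0983) or with the trend removed (log2 fold change 0.41 before and 0.22 after). Of 76 mitochondrial ribosomal proteins, 15 fell and 4 rose (10 and 2 adjusted over the list alone, camera adjusted p = 0.354), among them Mrpl4 with a log2 fold change of -0.74 and the locus shared by Mrps6 and Slc5a3 with 0.47. The share of these that fell was near that over all loci, where 2224 of 11767 were lower. Removing the trend gave 2 lower and 4 higher. Within replicates 2 and 3 and with fry this list passed as lower (adjusted p = 0.0463 and 0.0401, 2 of 29 alternatives, against adjusted p = 0.836 over the 6 libraries with an estimated correlation). Of 76 cytosolic ribosomal proteins, 21 fell and 5 rose (25 and 5 adjusted over the list alone, camera adjusted p = 0.416), and their reads can be shared with pseudogenes. Here 5 were lower and 6 higher with the trend removed. Rplp1 had a log2 fold change of -2.36 (SE 0.52) and Rpl36 of -1.33, whereas Rpl15 had 0.33 and Rpl27a 0.46. With the GC and length trend removed Mrpl4, Rplp1 and Rpl36 did not pass (log2 fold changes -0.21, -1.91 and -0.74), and Rpl15 passed at 0.53. Calls were lost without Control 2 or Control 3 for Rplp1 (adjusted p 0.0642 to 0.0692) and without Cocktail 2, Control 1 or Control 3 for Rpl27a (adjusted p 0.0560 to 0.0714).

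Genes of T cell activation and the immediate early response were lower, with 8 of 35 tested members lower, 1 higher and 26 not passing, in the same numbers adjusted over the list alone. Junb had a log2 fold change of -2.41 (SE 0.20, adjusted p 0.00340), and Nr4a1, a nuclear receptor induced by antigen receptor signals, fell from 36.4 ± 3.65 to 22.5 ± 0.987 FPKM. Il2ra, which encodes CD25, rose from 1.44 ± 0.0802 to 2.02 ± 0.208 FPKM. That call was lost when any library other than Cocktail 1 was left out (adjusted p 0.0667 to 0.110) and with the GC and length trend removed (log2 fold change 0.31 before and 0.15 after). Nr4a3 was at 5.81 ± 0.265 FPKM in Cocktail and 4.38 ± 0.702 FPKM in Control (adjusted p 0.0543), and passed as higher with the trend removed (log2 fold change 0.35 before and 0.59 after, adjusted p 0.0168), within replicates 2 and 3 (adjusted p 0.0340) and without Control 1 (adjusted p 0.0413). Other scalings, library weights, the replicate block and the term for replicate 1 also gave Nr4a3 as higher. The list median was -0.20 (camera adjusted p = 0.0342, and adjusted p = 0.836 with an estimated correlation). With the trend removed the list median was -0.047, with 4 members lower and 1 higher, and the list did not pass (adjusted p = 0.220). Nr4a1 did not pass either (log2 fold change -0.67 before and -0.32 after), and Junb passed at -1.85 (adjusted p 0.00786). The list also did not pass without Cocktail 2, Cocktail 3 or Control 1 (adjusted p = 0.0996, 0.0637 and 0.0640) or after median-of-ratios scaling (adjusted p = 0.0517). Alongside, with no trend removed, the log2 fold change of Hbb-b1 was -3.01 and the medians of B cell and antigen presenting cell markers were -0.46 and -0.52. The list passed in 17 of 29 alternatives, with adjusted p from 0.00105 to 0.836.

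Type I interferon response genes were higher in Cocktail, with 13 of 46 tested members higher, 3 lower and 30 not passing, in the same numbers adjusted over the list alone. Rtp4 rose from 21.5 ± 1.03 to 31.9 ± 2.39 FPKM (log2 fold change 0.54, SE 0.074, adjusted p 0.00556) and Trim30a from 44.8 ± 2.65 to 59.1 ± 0.584 FPKM. Loci shared by Lgals3bp and Cant1 and by Isg20 and Aen fell, from 84.3 ± 4.26 to 61.9 ± 3.24 FPKM and from 20.1 ± 1.55 to 15.0 ± 0.257 FPKM. They did not pass with the GC and length trend removed (log2 fold changes -0.038 and -0.011). The list median was 0.18 (camera adjusted p = 0.00420, and adjusted p = 0.836 with an estimated correlation). Within replicates 2 and 3 of both groups the list did not pass (adjusted p = 0.163), nor with library weights or with fry (adjusted p = 0.0855 and 0.179). With the trend removed over all 6 libraries it passed (median 0.15, adjusted p = 0.000238, and adjusted p = 0.674 with an estimated correlation), with 4 members higher and 0 lower. Trim30a then had a log2 fold change of 0.23 (0.40 before). The same comparison with no trend removed gave Hbb-b1 a log2 fold change of -3.01, and B cell and antigen presenting cell markers medians of -0.46 and -0.52. The list passed in 23 of 29 alternatives, with adjusted p from 0.000107 to 0.836. Of 28 interferon gamma response genes, 5 rose and 6 fell, also adjusted over the list alone. The list did not pass (camera adjusted p = 0.634, upward, with a median of 0.011 and a mean of -0.059), and 2 were higher and 2 lower with the trend removed. The GTPase genes Gbp8 and Ifi47 had log2 fold changes of 0.40 and 0.49, and Tap2 and Psmb10, genes of antigen processing, -0.83 and -0.90. Removing the trend gave 0.23 for Gbp8, -0.33 for Tap2 and -0.49 for Psmb10, all still past the threshold. Ifi47 did not pass without Control 2 or Control 3 (log2 fold changes 0.43 and 0.50, adjusted p 0.0533 to 0.0581) or with the trend removed (0.41, adjusted p 0.0601), although its fold change stayed near that size.

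Among 26 naive T cell and quiescence genes, 7 fell and 0 rose, also adjusted over the list alone. The list did not pass (camera adjusted p = 0.219, and 0.0262 with the GC and length trend removed, or adjusted p = 0.474 with an estimated correlation as well, within 0.0262 to 0.836 over 29 alternatives, of which 5 passed). Ccr7, a receptor that guides T cells to lymph nodes, fell from 309 ± 23.3 to 210.4 ± 6.77 FPKM (log2 fold change -0.55, SE 0.082, adjusted p 0.00702). Id3, a transcriptional regulator, fell from 19.4 ± 0.653 to 11.2 ± 1.05 FPKM (log2 fold change -0.74, and -0.40 with the trend removed). After this correction 5 members were lower and 0 higher. Of 19 gut homing and trafficking receptors, 5 fell and 0 rose (5 and 1 adjusted over the list alone, camera adjusted p = 0.448). Itgb7, the beta chain of gut homing integrins, fell from 300.5 ± 22.8 to 197 ± 8.63 FPKM, and the locus shared by S1pr4 and Ncln from 98.9 ± 4.62 to 52.3 ± 3.86 FPKM. With the trend removed 2 receptors were lower and 0 higher. Itgb7 did not pass (log2 fold change -0.61 before and -0.17 after), and the S1pr4 locus passed (-0.91 before and -0.41 after).

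Of 21 T cell identity genes, 5 fell and 1 rose, also adjusted over the list alone (camera adjusted p = 0.449). The receptor signalling kinase gene Zap70 fell from 71.7 ± 4.15 to 46.9 ± 1.12 FPKM, and Lat, an adaptor in the same pathway, rose from 594 ± 33.7 to 755 ± 39.7 FPKM. Cd4 was at 341 ± 30.3 FPKM in Cocktail and 352 ± 22.5 FPKM in Control without passing. Of 30 memory and effector genes, 5 fell and 1 rose (4 and 1 adjusted over the list alone, camera adjusted p = 0.448). Lgals1, a galectin, fell from 99.4 ± 15.3 to 57.9 ± 10.2 FPKM, and Cd44 was at 22.7 ± 1.47 FPKM in Cocktail and 20.0 ± 0.663 FPKM in Control without passing (adjusted p 0.0923). Cd44 passed as higher without Cocktail 1 (adjusted p 0.0387), within replicates 2 and 3 (0.0413), after median-of-ratios scaling (0.0271) or quantile normalization (0.0165), and with library weights (0.0178). With the GC and length trend removed 0 identity genes were lower and 1 higher, and of the memory and effector genes 1 was lower and 0 higher. Zap70 and Lgals1 did not pass then (log2 fold changes -0.60 and -0.77 before, -0.12 and -0.47 after). Lat passed with a larger rise (log2 fold change 0.35 before and 0.80 after, adjusted p 0.00741). Its uncorrected call was lost when any library other than Cocktail 1 was left out (adjusted p 0.0830 to 0.136), and that of Lgals1 without Cocktail 2, Control 2 or Control 3 (adjusted p 0.0573 to 0.0661). Quantile normalization gave Lat a log2 fold change of 0.55.

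The helper T cell lists did not pass as groups, and the transcription factor genes Tbx21, Gata3 and Foxp3 did not pass either. Tbx21, the Th1 factor, was at 2.66 ± 0.684 FPKM in Cocktail and 2.97 ± 0.361 FPKM in Control, Gata3, the Th2 factor, at 16.4 ± 1.06 FPKM in Cocktail and 20.0 ± 3.20 FPKM in Control, and Foxp3 at 4.77 ± 0.662 FPKM in Cocktail and 4.35 ± 0.835 FPKM in Control. Their adjusted p was 0.530, 0.147 and 0.553, and Gata3 passed as lower without Control 2 (adjusted p 0.0460) and with library weights (0.0471). Foxp3 passed as higher with the GC and length trend removed and a term for replicate 1 (0.0308). The cytokine genes Il2, Il4 and Il17a lay below the filter, with means of 0.279 ± 0.0596, 0.443 ± 0.105 and 0 ± 0 FPKM in Cocktail and 0.255 ± 0.104, 0.488 ± 0.278 and 0.0116 ± 0.0102 FPKM in Control. Of 22 Th1 and cytotoxic genes, 3 fell and 0 rose (0 fell adjusted over the list alone, camera adjusted p = 0.569). Of 7 Th2 genes 1 fell, also adjusted over the list alone (camera adjusted p = 0.546). Of 11 Th17 genes 1 fell and 1 rose, also adjusted over the list alone (camera adjusted p = 0.546). Of 14 regulatory T cell genes, 4 fell and 1 rose (4 and 2 adjusted over the list alone, camera adjusted p = 0.634). Of 16 genes of follicular helper cells and inhibitory receptors 1 fell and 1 rose (0 and 0 adjusted over the list alone, camera adjusted p = 0.426). Removing the GC and length trend gave 0 Th1 genes lower and 1 higher, 0 Th2 genes lower and 1 higher, and in the Th17 list 1 lower and 0 higher. In the regulatory and the follicular helper lists 0 were then lower and 0 higher. Ctla4, an inhibitory receptor on both of these lists, fell from 8.02 ± 1.52 to 5.51 ± 0.624 FPKM. That call was lost when any of the 6 libraries was left out (adjusted p 0.0662 to 0.139), within replicates 2 and 3 (adjusted p 0.0647), and with the trend removed (log2 fold change -0.46 before and -0.58 after, adjusted p 0.0609).

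**Figure D3:**
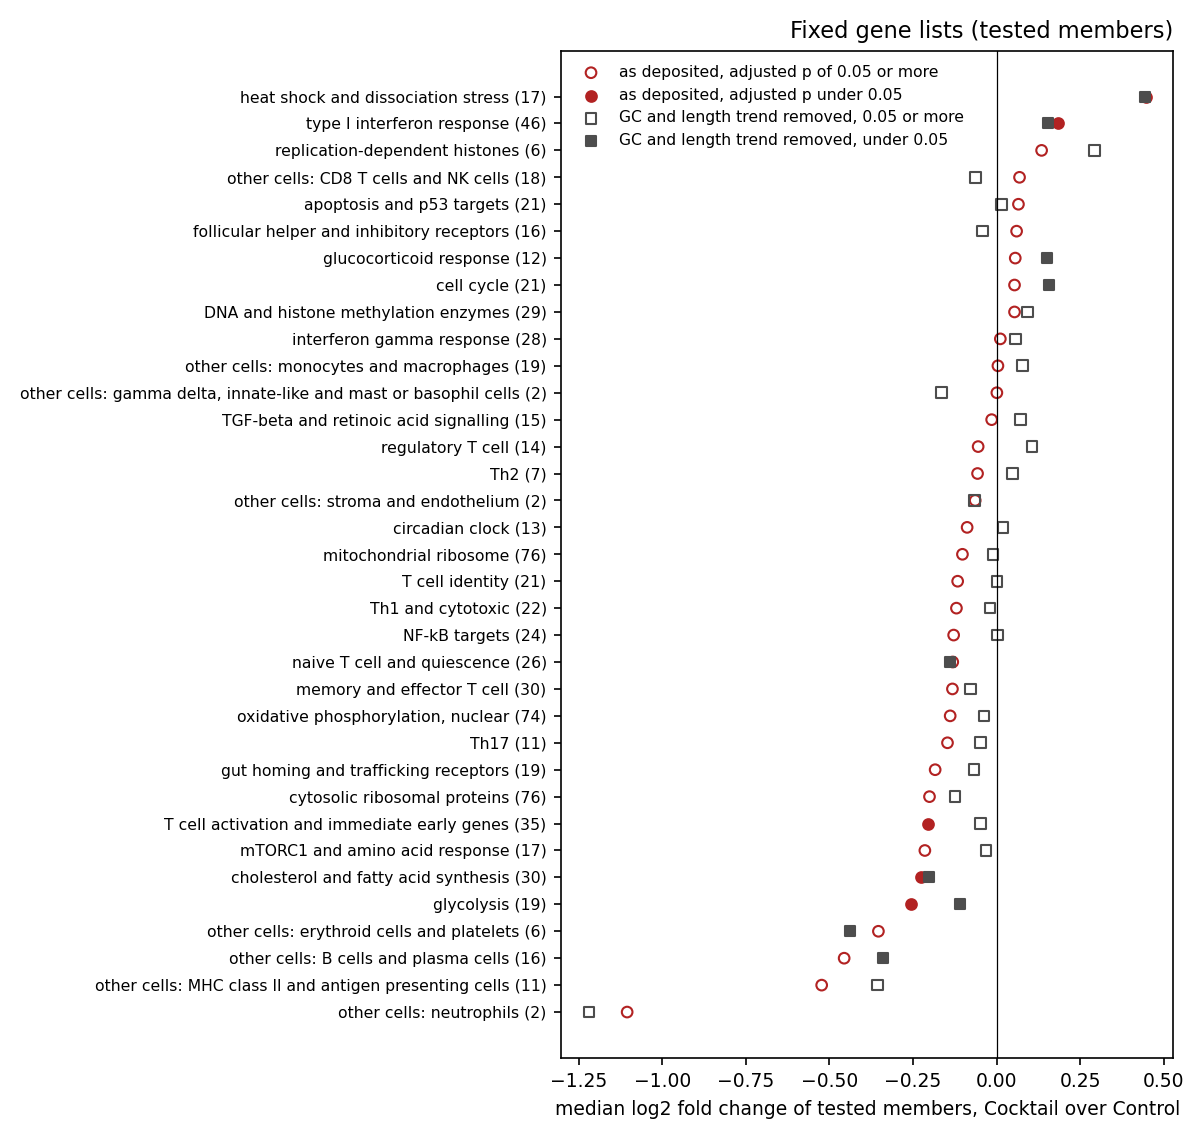
Median log2 fold change (Cocktail over Control, horizontal axis) of the tested members of 35 fixed gene lists (vertical axis, number of tested members in parentheses), as deposited (circles) and with the GC and length trend removed (squares), filled where the camera adjusted p was under 0.05 with a preset correlation. The heat shock list lies at 0.45 and 0.44, and no list passed with an estimated correlation (lowest adjusted p = 0.836 as deposited and 0.454 with the trend removed).

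Markers of red blood cells and of B cells were lower in Cocktail in some members. Of 6 erythroid and platelet markers, 4 fell and 0 rose, also adjusted over the list alone (camera adjusted p = 0.0717, and 0.0344 with the GC and length trend removed, or adjusted p = 0.454 with an estimated correlation as well, within 3.64e-05 to 0.836 over 29 alternatives, of which 4 passed). The haemoglobin beta locus (Hbb-b1) fell from 27.0 ± 9.93 to 2.40 ± 1.02 FPKM (log2 fold change -3.01, SE 0.33, adjusted p 0.00380), and the haemoglobin alpha locus (Hba-a1) from 7.94 ± 2.53 to 0.481 ± 0.175 FPKM. Without Control 3 the erythroid list passed (adjusted p = 0.0470, against adjusted p = 0.836 over the 6 libraries with an estimated correlation), and 4 members were lower and 0 higher with the trend removed. Of 16 B cell and plasma cell markers, 2 fell, Cd79a from 12.5 ± 4.46 to 6.34 ± 0.756 FPKM and Cd74 from 149 ± 49.7 to 80.0 ± 10.5 FPKM, and 0 adjusted over the list alone (camera adjusted p = 0.0912, and 0.0344 with the trend removed, or adjusted p = 0.815 with an estimated correlation as well, within 0.00321 to 0.847 over 29 alternatives, of which 7 passed). Cd79a and Cd74 did not pass with the trend removed (log2 fold changes -0.84 and -0.85 before, -0.57 and -0.54 after) or without Cocktail 2 or Cocktail 3. Cd79a also did not pass without Control 3 (adjusted p 0.0529 to 0.0995 over these libraries), nor Cd74 without Control 1 (adjusted p 0.0605 to 0.115) or within replicates 2 and 3 (adjusted p 0.0566). The B cell list passed as lower without Cocktail 1 or Control 3 (adjusted p = 0.0157 and 0.00394) and within replicates 2 and 3 (adjusted p = 0.0317), against adjusted p = 0.847 with an estimated correlation. Of 11 markers of antigen presenting cells, 4 fell and 0 rose (6 and 1 adjusted over the list alone, camera adjusted p = 0.243), among them H2-DMa, from 18.3 ± 1.86 to 8.89 ± 0.973 FPKM (log2 fold change -0.97, and -0.64 with the trend removed). Removing the trend gave 2 of these markers lower and 0 higher.

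Of 19 monocyte and macrophage markers, 1 fell, the locus shared by Apoe and Tomm40, from 34.0 ± 5.94 to 18.3 ± 1.52 FPKM, also adjusted over the list alone (camera adjusted p = 0.972, upward, with a median of 0.0039 and a mean of -0.061). It did not pass with the GC and length trend removed (log2 fold change -0.85 before and -0.34 after). Of 18 markers of CD8 T cells and NK cells 1 rose, Klrd1, from 41.4 ± 4.34 to 53.1 ± 5.14 FPKM, and 0 adjusted over the list alone (camera adjusted p = 0.634). That call was lost without Cocktail 1, Cocktail 2, Control 1 or Control 2 (adjusted p 0.0787 to 0.142) and within replicates 2 and 3 (log2 fold change 0.31, adjusted p 0.137). It was also lost with the trend removed (log2 fold change 0.35 before and 0.14 after, adjusted p 0.346). The 2 tested neutrophil markers did not pass, S100a8 at 1.40 ± 1.77 FPKM in Cocktail and 3.38 ± 1.97 FPKM in Control and S100a9 at 0.907 ± 0.875 FPKM in Cocktail and 3.25 ± 1.63 FPKM in Control (camera adjusted p of the list = 0.448). Both passed as lower without Cocktail 3 (adjusted p 0.0409 and 0.0426). S100a9 also passed with library weights. Of 2 tested markers of innate-like cells and 2 of stroma 0 rose and 0 fell, also adjusted over each list alone (camera adjusted p = 0.984 and 0.931), and 1 of the innate-like markers was lower with the trend removed.

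The largest fall on the log scale was at a locus named for Gstp1, Gstp2 and BC021614, the first pair of which encode glutathione transferases. It was listed at 0 in the 3 Cocktail libraries and at 311, 322 and 313 FPKM in the Control libraries. A listed 0 need not mean absence here, since Eef1a1, a translation factor that every cell uses, was listed at 0 in the 6 libraries. Selplg, which encodes a selectin ligand, was split over 2 loci that moved apart. The locus with the largest rise held 14.3, 15.1 and 14.7 FPKM in Cocktail and 8.20, 0 and 0 FPKM in Control. Its call was lost when any library other than Control 1 was left out (adjusted p 0.0760 to 0.13). The more abundant Selplg locus fell from 226 ± 29.5 to 131 ± 19.6 FPKM (log2 fold change -0.79, SE 0.14, adjusted p 0.0123). Neither locus passed with the GC and length trend removed, where the log2 fold change of the rising locus went from 2.91 to 3.21 (adjusted p 0.0583) and that of the falling locus from -0.79 to -0.48 (adjusted p 0.0530). Of the 10 largest rises, 6 were at loci without a gene name, and of the 10 largest falls 5.

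The authors' deposited table lists 2179 loci, 413 higher and 1766 lower in Cocktail once its ratio of Control over Cocktail is turned. Of 308 listed as higher that were tested here, 232 were also called higher, where independent lists would share 27.5 (Fisher's exact test, p = 3.55e-184). Of 1575 listed as lower, 1375 were also called lower, where independent lists would share 298, with an exact p too small to represent. No locus was called in the opposite direction, and both tables come from the same libraries, so the overlap is a description. In the authors' deposited table the named loci with the largest rises were Frmd8, at a log2 ratio of 3.15, and the Mir17hg microRNA cluster, at 2.60. Frmd8 held 4.53, 43.0 and 44.2 FPKM in the Cocktail libraries and 3.14, 4.11 and 3.06 FPKM in the Control libraries. The Mir17hg locus held 83.3 FPKM in Cocktail 3 and at most 6.05 FPKM in the others. The largest finite fall in the authors' deposited table, Rpl23a at -4.91, rested on Control 3 with 51.6 FPKM, against at most 0.870 FPKM in the others.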

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

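The GC and length correction, the term for replicate 1, the fits on replicates 2 and 3, the fits without loci at 0 or with loci of 1 name summed, and the fit on loci with GC values were chosen after the data were seen, and the other alternatives before. Of 59 named genes past the threshold, 0 reversed and 26 passed in every setting that tested them. Besides the losses given in the main text, calls were lost with no filter (Cd74, Cd79a, Ctla4, Il2ra, Klrd1, Lat, Rplp1, Top2a, Uqcrb and the rising Selplg locus), with the replicate block (Cd74, Il2ra and Klrd1), with other scalings (Cd79a and Ctla4), with a smaller pseudocount (the rising Selplg locus), without the intensity trend (Klrd1), with library means kept (Eed, Gbp8, Mrps6, Top2a and Trim30a) and with the correction within replicates 2 and 3 (Kdm6b, Top2a and Trim30a). Over all loci, 395 of 3032 calls had a fold change of the other sign with the GC and length correction, 325 with library means kept and 431 with the correction within replicates 2 and 3. The count tools planned for whole reads were not run, since whole reads could not be had. Loci counted as higher (1050 as deposited) numbered 1779 with median-of-ratios scaling, 2390 with quantile normalization, 2502 with library weights, 485 with the GC and length correction, 225 with its earlier version that kept library means, 2228 with the replicate 1 term, 1705 within replicates 2 and 3, 1870 at an adjusted p under 0.1, 16 with an absolute log2 fold change of at least 1, and 200 to 1518 with 1 library left out. Loci counted as lower (2224) numbered 443 with the correction, 722 with library means kept, 1276 with correction and replicate 1 term, 1030 with correction within replicates 2 and 3, 112 with an absolute log2 fold change of at least 1, and 1134 to 2244 with 1 library left out. The cause was not tested beyond the smaller number of libraries or loci where these were left out.

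The replicate block gave 1806 higher and 2819 lower loci, and with the GC and length correction 1077 and 985. Residuals of libraries that share a number correlated at 0.391, -0.0199 and 0.297. Cocktail 1 and Cocktail 3 correlated best with the Control library of the same number, and Cocktail 2 did not. Whether the numbers pair the samples therefore stays open, and the labels do not say. Under the block each of the 5 lists passed, and under block and correction together the activation list did not (adjusted p = 0.287).

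Of 35 lists, 5 passed as planned, 11 without the filter, 9 with the correction, 3 on loci with GC values uncorrected, 11 with fry, 27 with fry in either direction, 0 with an estimated correlation with or without the correction, and 3 to 7 with 1 library left out. The regulatory T cell and antigen presenting cell lists passed at a mean of at least 5 FPKM (adjusted p = 0.0323 and 0.0346) and the neutrophil list without the filter (adjusted p = 0.00323), against adjusted p = 0.893, 0.845 and 0.836 with an estimated correlation. Of the 29 alternatives, only fry passed the NF-kB, cytosolic ribosomal, gut homing and mTORC1 lists (adjusted p = 0.0246, 0.0339, 0.0246 and 0.0243, against adjusted p = 0.836, 0.836, 0.836 and 0.836 with an estimated correlation). Outside the 29, these lists also passed fry in either direction, and gut homing passed fry with the correction (adjusted p = 0.0293). A list can pass fry without standing out from the other loci. With an estimated correlation the 5 lists had an adjusted p of 0.836, and with the correction as well 0.454 for heat shock, cholesterol and glycolysis, 0.674 for interferon and 0.815 for activation. The activation list had an adjusted p of 0.0517 with median-of-ratios scaling, 0.22 with the correction, 0.436 with library means kept, 0.0619 on loci with GC values, 0.267 with correction and replicate 1 term, 0.0884 with correction within replicates 2 and 3, and 0.00933 to 0.0996 with 1 library left out. The interferon list had 0.0855 with library weights, 0.163 within replicates 2 and 3, 0.118 there with the correction, and 0.179 with fry. The glycolysis list had 0.0567 with the correction and library means kept, the version run before the one used, 0.0619 on loci with GC values, 0.0884 with the correction within replicates 2 and 3, and 0.0231 to 0.0667 with 1 library left out. The cause was not tested.

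Genes that did not pass changed sign in some settings, with log2 fold changes given here. With the correction (also with the block or the replicate 1 term) Ifng was at -0.10, Tbx21 at 0.36, Gata3 at 0.076, Cd4 at 0.029 and Bag3 at 0.13. With library means kept Ifng was at -0.18, Tbx21 at 0.29, Bag3 at 0.051 and Xist at -0.037. With the correction within replicates 2 and 3 Ifng was at -0.012, Tbx21 at 0.18, Gata3 at 0.040, Cd4 at 0.058, Bag3 at 0.16 and Xist at -0.034. Cd4 was at 0.14 with quantile normalization. With 1 library left out Ifng lay from -0.0027 to 0.14, Cd4 from -0.10 to 0.023 and Hmox1 from -0.68 to 0.023. The cause was not tested.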

Other observations

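The gene lists in this part and their camera tests were fixed with the others. The tests of explanations for the GC, heat shock and Gstp patterns and of the splits of the libraries below were chosen after the results were seen, except the one on GC bias from library to library. The lists of the amino acid response, of retinoic acid signalling and of the clock did not pass, and most falls among their members were not called with the GC and length trend removed. Of 17 mTORC1 and amino acid response genes, 3 rose and 7 fell, also adjusted over the list alone (camera adjusted p = 0.435), against 4 higher and 0 lower with the trend removed. Ddit4 had a log2 fold change of 1.05 and Asns, asparagine synthetase, rose from 4.81 ± 0.637 to 8.15 ± 1.11 FPKM. Of 15 genes of TGF-beta and retinoic acid signalling, 4 fell and 2 rose (6 and 2 adjusted over the list alone, camera adjusted p = 0.477), and the retinoic acid receptor genes Rara and Rarg fell from 25.5 ± 3.49 to 12.4 ± 1.68 FPKM and from 15.4 ± 1.38 to 7.78 ± 0.253 FPKM. Removing the trend gave 2 lower and 1 higher, and Rara and Rarg went from log2 fold changes of -0.98 and -0.89 to -0.48 and -0.37. Of 13 clock genes 4 fell and 0 rose, also adjusted over the list alone (camera adjusted p = 0.505), among them Per1 and Nr1d1 with log2 fold changes of -0.63 and -0.49. Neither passed with the trend removed (-0.13 and -0.12), where 0 clock genes were lower and 0 higher. Per1 did not pass without Control 3 (adjusted p 0.0581) nor Nr1d1 without Cocktail 2 (adjusted p 0.0565). Of 12 glucocorticoid response genes 2 rose, Ddit4 among them, and 1 fell (3 and 1 adjusted over the list alone, camera adjusted p = 0.436, and 0.0430 with the trend removed, or adjusted p = 0.454 with an estimated correlation as well, within 0.0232 to 0.836 over 29 alternatives, of which 3 passed). In this list 3 were higher and 0 lower with the trend removed.

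Of 21 cell cycle genes, 6 rose and 1 fell (7 and 1 adjusted over the list alone, camera adjusted p = 0.229, and 0.0344 with the GC and length trend removed, or adjusted p = 0.454 with an estimated correlation as well, within 0.000621 to 0.840 over 29 alternatives, of which 3 passed). Rrm2, a subunit of ribonucleotide reductase, rose from 2.18 ± 0.339 to 3.83 ± 0.190 FPKM, and Top2a, a topoisomerase of dividing cells, from 2.30 ± 0.488 to 3.84 ± 0.263 FPKM. The Top2a call was lost without Cocktail 2, Cocktail 3 or Control 3 (adjusted p 0.0574 to 0.0674). Removing the trend gave 3 cell cycle genes higher and 0 lower. Of 21 apoptosis and p53 target genes 4 rose and 3 fell (5 and 4 adjusted over the list alone, camera adjusted p = 0.546), among them Fas with 0.37 and Bax with -0.72 on the log2 scale. Of 24 NF-kB targets 7 fell and 2 rose (9 and 2 adjusted over the list alone, camera adjusted p = 0.354), with Ltb, a lymphotoxin gene, falling from 428 ± 35.3 to 256 ± 15.9 FPKM. Fas, Bax and Ltb did not pass with the trend removed (log2 fold changes 0.37, -0.72 and -0.74 before, 0.18, -0.22 and -0.18 after). There, 1 of the apoptosis and p53 target genes was higher and 0 lower, and 1 of the NF-kB targets was higher and 0 lower. Of 29 DNA and histone methylation enzymes, a list that also holds deacetylases, 5 rose and 7 fell (8 and 7 adjusted over the list alone, camera adjusted p = 0.505, upward, with a median of 0.054 and a mean of -0.021). Eed of the Polycomb complex rose from 32.5 ± 1.69 to 45.4 ± 3.84 FPKM and the demethylase gene Kdm6b fell from 19.4 ± 2.27 to 11.4 ± 0.977 FPKM (log2 fold change -0.71, and -0.34 with the trend removed). Removing the trend gave 3 of 28 such enzymes higher and 1 lower. Of 6 replication-dependent histone genes 1 rose, also adjusted over the list alone (camera adjusted p = 0.650).

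GC-rich transcripts were lower and GC-poor transcripts higher in Cocktail (r = -0.66 across genes). The gap between the nearest Cocktail and Control library in the correlation of their deviations with GC content was 3.28 times the larger range within a group. This passed the cut-off set beforehand and argues only weakly against a GC bias that varied from library to library without regard to group. Such a bias could still line up with the groups by chance, as 10 splits of 6 libraries give no share under 0.1. Cocktail 1 alone is argued against, since the correlation was -0.65 without it. A GC bias shared by the libraries of a group, from library preparation or sequencing, cannot be told apart from an effect of the parents' treatment or of the water after weaning, because the groups are the only split the labels give and each would yield the correlation of -0.66. Which of these may be the source stays open.

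Heat shock genes were higher in Cocktail with a preset correlation, and their list did not pass when it was estimated (adjusted p = 0.836 with an estimated correlation). The trend on GC content and length as their whole cause is argued against, since the list passed with the trend removed (adjusted p = 1.13e-08, against adjusted p = 0.454 with an estimated correlation) and its median went from 0.45 to 0.44. Handling stress that raises immediate early genes with heat shock genes is argued against only weakly, since the median log2 fold change of 13 immediate early genes was -0.32 with the trend removed (SE 0.21, and -0.51 with SE 0.24 before), with 1 higher, Nr4a3, and 3 lower. These genes belong to the activation list, already seen to be lower, and the SE is across genes, which are not independent replicates. A day or handling step shared by the libraries of a group cannot be told apart from the parents' treatment or the water. In 12 of 17 members every Cocktail value lay above every Control value, which either may give. Over all tested loci the groups did not overlap, in either direction, in 48.7%.

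The Gstp locus was listed at 0 in the 3 Cocktail libraries and at 311 FPKM or more in the Control libraries. A failed estimate in the authors' processing stays open, since 4 other loci of at least 100 FPKM in a library were listed at 0 in another, where the test had asked for 5 with this locus left out, and Gapdh was at 0.268 to 0.805 FPKM. Those 4 were Snora31 and loci without a gene name, at 0 in 1 or 2 libraries and never in a whole group, so they are unlike the Gstp locus. Transcripts absent in Cocktail should appear in the authors' deposited table with an infinite ratio, as 6 loci of at most 3.62 FPKM did. That table had 0 entries for the locus, so this was not met, and absence stays open as well. The parents' treatment, or a strain difference at this locus, may give such values too and was not tested.

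The 10 splits of the 6 libraries into 3 and 3 are too few for a share under 0.05. The real split gave 3274 calls, the only 1 of the 10 with as many, and the highest other split gave 1. With the GC and length correction the real split gave 928 calls and the other splits 0. Every other split mixes Cocktail and Control libraries, so a difference between the groups, whatever its source, widens the spread within it. Few calls were therefore bound to appear there, and these counts do not measure what chance gives.

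Replicate 1 of both groups differed from the other libraries in 231 higher and 511 lower loci in the model with a term for it.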
